A study of Mus musculus with 9 samples.

How the data were processed

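RNA of OT-I CD8 T cells was extracted with the RNeasy Plus Micro kit and made into libraries with the TruSeq Stranded mRNA kit, per the labels' protocols. The 9 libraries form 3 groups of 3, taken from the sample titles and the tissue labels: naive cells from the spleen, primed cells from the spleen and primed cells from the MLN. The labels do not state the gate used to isolate the cells, the time after priming, or whether libraries with the same number share an animal.

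The deposited table holds FPKM, fragment numbers scaled by transcript length and by the mapped fragments of the library, with 1 value per gene and library. The values were made with TopHat and Cufflinks on the mouse build mm10, per the submitters' processing notes; versions, filters and the use of strand in quantification are not given in the sources used here. FPKM divide by transcript length and library total, so they do not keep read numbers, and a few abundant genes can shift all others. A second deposited table, named as transcript values, was identical to the gene table byte for byte and was not used. Total FPKM were 612887 to 720165 per library, so the values do not sum to a fixed total and differences in scale between libraries remain in them. The read depth is unknown, and no counting error is given.

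The table has 24067 rows, of which 131 carry no gene symbol and hold 0.0479% of the FPKM; they were left out, which left 23936 genes. Genes with at least 1 FPKM in at least 3 libraries were tested, 10185 in all. Values were used as deposited, without further scaling, as log2(FPKM + 1), a scale on which changes of low genes are understated. One linear model over all 9 libraries was fitted with limma 3.58.1 in R 4.3.3 (limma-trend), with contrasts for the 3 pairs of groups, two-sided tests and Benjamini-Hochberg adjustment over the genes tested, at an adjusted p of 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Values of all replicates are printed as mean ± SD, and log2 changes with the standard error of the model.

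Gene lists and marker lists, 21 and 11, were fixed before the data were examined, as were the groups, tests, the rule for named genes and the alternatives, except those named below as added. Lists with at least 5 tested members entered camera (limma) with its preset correlation between genes of 0.01, adjusted over those lists. Camera was run again with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in one direction, was run as an alternative. Unlike camera, fry does not set a list against the other genes, so many lists can pass where most genes change. A list's genes are also counted at an adjustment over the list alone. Some genes belong to several lists. Members without a value in the table, such as Zfp683, Trac and the immunoglobulin constant genes, were not analysed here.

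Named genes are, for each comparison, the 10 with the largest rise and the 10 with the largest fall among genes that passed, had no overlap between the replicate values of both groups and reached a mean of 5 FPKM in the higher group, without predicted or clone-named models, small RNAs, ribosomal protein pseudogenes and receptor segments. Members of the lists, Ccr9 and Itgae are named as well, with their values. Some genes that meet the rule or belong to the lists are not reported here.

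The responses of both primed groups against naive were compared by Pearson correlation and covariance across genes, beside 100 simulations of unchanged groups sharing the naive libraries. The model and the list test were tested on simulated data for MLN-primed against spleen-primed, with 200 of 10185 genes changed in each of 10 sets. Of these, 51.9% were recovered at a log2 change of 0.5, 91.0% at 1 and 98.3% at 2, with 5.16% false calls. A list of changed genes was called in 10 of 10 sets and a random list in 0 of 10. Values of the simulated genes were drawn independently, so this leaves untested how the list test behaves where genes of a list vary together.

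Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM in 3 libraries, median-of-ratios scaling, quantile normalisation, variance models without trend or with robust estimation, only the libraries of the groups compared, the replicate number as a block, each library left out in turn, and the other list tests. After the data were examined, removal of a trend with transcript length and GC content from each library, the length trend of each library as a covariate, and a fit without spleen-primed 3 and MLN-primed 1 were added. That last fit leaves only negative length trends among spleen-primed and only positive ones among MLN-primed libraries, so group and trend coincide in it. The covariate is a slope fitted to the same values centred on each group, so it leaves group differences unchanged and alters only the spread. Length and GC content came from the GENCODE annotation of GRCm38, the assembly that mm10 names, and 99.0% of the tested genes had a value. Gene families by symbol were also screened after the data were examined.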

Results

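RNA sequencing of OT-I CD8 T cells was deposited for 9 libraries in 3 groups of 3. OT-I cells are mouse CD8 T cells whose transgenic receptor recognises an ovalbumin peptide on MHC class I. The naive cells came from the spleen, the spleen-primed cells from the spleen and the MLN-primed cells from the MLN, the lymph node that drains the intestine. Sample titles add "iv" for the spleen-primed and "oral" for the MLN-primed cells, so organ and these title words change together between the primed groups and their effects cannot be separated here. The time after priming was not given in the sources used here. The series title concerns retinoic acid signalling during priming and the later formation of intestinal CD103+ resident memory cells. Values were FPKM per gene, and 10185 genes reached 1 FPKM in at least 3 libraries and were tested. FPKM totals were 612887 to 720165 per library and 9469 to 9667 genes reached 1 FPKM. Read numbers are unknown, because FPKM do not keep them. The labels do not say that the 3 libraries of a group came from different animals, so p-values measure the spread between these libraries, which may be technical.

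Naive libraries stood far from both primed groups. The first principal component held 87.2% of the variance and parted naive from primed libraries, and the second held 5.68% and parted MLN-primed from spleen-primed libraries. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.987 to 0.995 within groups, 0.971 to 0.982 between the primed groups, and 0.787 to 0.826 between primed and naive libraries. The 10 most abundant genes took 14.6% of all FPKM in naive, 9.51% in spleen-primed and 8.74% in MLN-primed libraries on average. Within the primed groups, libraries also differed by a trend with transcript length. Each doubling of length changed log2(FPKM + 1), relative to the group, by -0.105 in MLN-primed 1 and by 0.0895 in spleen-primed 3, the outermost libraries.

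**Figure D1:**
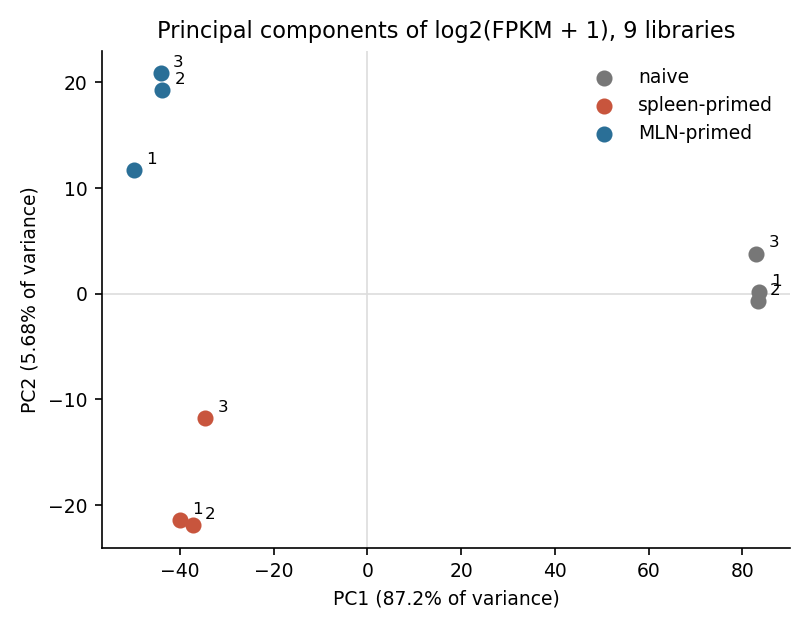
Scores of the 9 libraries on the first (x axis, 87.2% of variance) and second (y axis, 5.68%) principal component of log2(FPKM + 1) over the genes tested. Each point is a library, numbered by replicate and coloured by group, and the 3 naive libraries lie apart on the x axis while the primed groups part on the y axis.

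All 9 libraries held the transcripts of CD8 T cells. Cd8b1 was at 1252 ± 101 FPKM in naive, 861 ± 13.2 in spleen-primed and 601 ± 26.7 in MLN-primed cells (mean ± SD, n = 3, as for all FPKM values with an error below), and Cd8a at 323 ± 45.6, 204 ± 5.78 and 178 ± 13.7. The activation marker Cd44 was at 2.91 ± 0.881, 24.1 ± 0.618 and 18.6 ± 1.02 FPKM, and granzyme B (Gzmb) at 2.3 ± 0.899, 1499 ± 153 and 1169 ± 87.1. List means of markers of other cell types lay far below that of the CD8 T cell identity list. They are given as mean log2(FPKM + 1) in naive, spleen-primed and MLN-primed libraries in that order, with the SD over 3 libraries. Such means hide high members, among them Gzma at 2529 and Itgax at 94.8 FPKM in spleen-primed cells. In naive cells Cd74 was at 55.4 and Pecam1, of the stromal and endothelial list, at 39.4 FPKM. B cell markers were at 0.415 ± 0.0102, 0.418 ± 0.0132 and 0.455 ± 0.030, plasma cell markers at 0.0567 ± 0.0511, 0.261 ± 0.0803 and 0.251 ± 0.0536, and stromal and endothelial markers at 0.466 ± 0.0182, 0.228 ± 0.0187 and 0.217 ± 0.027. Epithelial markers were at 0.141 ± 0.00447, 0.183 ± 0.0414 and 0.275 ± 0.0619, gamma delta T cell markers at 0.34 ± 0.174, 0.174 ± 0.050 and 0.0826 ± 0.0275, and red cell and platelet markers at 1.14 ± 0.551, 0.805 ± 0.382 and 0.537 ± 0.862. Myeloid markers were at 1.41 ± 0.47, 1.04 ± 0.116 and 0.644 ± 0.0417, and dendritic cell and MHC class II markers at 1.87 ± 0.223, 1.01 ± 0.112 and 0.989 ± 0.0381, both highest in naive libraries. NK cell markers, several of which effector CD8 T cells also express, were at 1.06 ± 0.302, 1.98 ± 0.0835 and 1.6 ± 0.0266. CD4 T cell markers were at 1.81 ± 0.0808, 1.03 ± 0.10 and 0.987 ± 0.0749, with Cd4 itself at 0.212, 0.0735 and 0.0786 FPKM, and the CD8 T cell identity list was at 8.71 ± 0.0612, 8.41 ± 0.00581 and 7.94 ± 0.0508.

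The comparison of MLN-primed with spleen-primed cells asks how the transcripts of both primed groups differ, with organ and the title words changing together. The gut-homing receptor gene Ccr9, whose product answers to a chemokine of the small intestine, differed most among genes named by the rule. It was at 20.4 ± 3.61 FPKM in MLN-primed and 0.0525 ± 0.0247 FPKM in spleen-primed cells, a log2 difference of 4.33 ± 0.15 (SE; limma, adjusted p = 7.94e-07). Itgae, which encodes the CD103 integrin chain that binds E-cadherin, was at 3.0 ± 0.262 against 0.245 ± 0.0513 FPKM (1.68 ± 0.14, adjusted p = 4.57e-05). Naive cells held more of both transcripts, 37.7 ± 6.35 FPKM of Ccr9 and 23.3 ± 4.8 FPKM of Itgae. All log2 changes here are on the log2(FPKM + 1) scale, which understates the change of genes near 0. In the mouse assembly GRCm38, Ccr9 (gene ID 12769) lies on chromosome 9 from 123767211 to 123783457 on the plus strand, and Itgae (gene ID 16407) on chromosome 11 from 73090505 to 73147449 on the plus strand, both protein-coding genes given with their RefSeq ends.

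Of 12 tested genes of retinoic acid signalling and response, 3 were higher in MLN-primed cells, namely Ccr9 (4.33), Hic1 (1.93) and P2rx7 (1.62), with log2 changes in parentheses, and 1, Rara (-0.84), was lower (4 higher and 4 lower adjusted over the list alone). Hic1, a transcriptional repressor, was at 9.91 ± 1.36 against 1.86 ± 0.163 FPKM, and P2rx7, an ATP-gated channel, at 2.83 ± 0.359 against 0.241 ± 0.0789 FPKM. The receptor gene Rara was at 6.96 ± 1.43 against 13.3 ± 3.0 FPKM. As a set the list did not pass in camera (adjusted p = 0.376, and adjusted p = 0.766 with an estimated correlation) but passed in fry (adjusted p = 5.40e-04), and its median log2 change was -0.02. Among genes linked to CD103+ resident memory, those of the list that is low in resident cells were mostly lower in MLN-primed cells. In that list 2 of 23 tested members were higher and 19 lower (camera, adjusted p = 3.57e-08, and adjusted p = 0.0801 with an estimated correlation), with a median log2 change of -0.73. Large falls were those of Cx3cr1 (-2.16), S1pr5 (-2.16) and Ly6c2 (-2.08), while Ccr7 (0.46) and Usp33 (0.25) were higher. The call of Ccr7 ended without spleen-primed 1 (0.38) or MLN-primed 3 (0.41). That of Usp33 ended without any single primed library except MLN-primed 1 (0.23 to 0.27), and also under median-of-ratios scaling (0.21) and quantile normalisation (0.23). Of the 29 tested genes of the list that is high in resident cells, 6 were higher and 5 lower (6 higher and 6 lower adjusted over the list alone; camera, adjusted p = 0.758, and adjusted p = 0.827 with an estimated correlation). The higher ones included Xcl1 (1.69), Itgae (1.68) and P2rx7 (1.62), and the lower ones Vps37b (-0.59) and Amica1 (-0.49).

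Most homing and egress receptors other than Ccr9 were lower in MLN-primed cells. Of 19 gut and tissue homing receptors, 11 were lower and 3 higher (3 higher and 13 lower adjusted over the list alone; camera, adjusted p = 1.43e-04, and adjusted p = 0.0801 with an estimated correlation). The members that were higher were Ccr9 (4.33), Gpr15 (1.31) and Gpr55 (0.58). The call of Gpr55 ended without any single library except spleen-primed 3 and MLN-primed 1 (0.46 to 0.58), and also with a pseudocount of 0.1 (0.67), with no filter and with only the libraries of both groups fitted (0.58 in both). The lower ones included the integrin genes Itgb1 (-1.62) and Itgal (-0.74) and the inflammatory chemokine receptor gene Ccr2 (-1.46). Itga4 and Itgb7, which encode the chains of a gut-homing integrin, did not pass, with Itga4 at 143 ± 22.8 against 160.1 ± 13.8 FPKM and Itgb7 at 438 ± 25.6 against 499 ± 33.3 FPKM (adjusted p = 0.301 and 0.0821). Itgb7 passed without spleen-primed 3 (-0.24), without both spleen-primed 3 and MLN-primed 1 (-0.28) and with the length trend of each library as a covariate (-0.18). That covariate leaves the difference itself unchanged and alters only the spread. Of 8 genes of lymphoid homing and egress, 6 were lower and 1 higher (camera, adjusted p = 9.06e-04, and adjusted p = 0.0933 with an estimated correlation). S1pr1 fell by 0.74 on the log2 scale, and the member that was higher was Ccr7, a call that ended without spleen-primed 1 (0.38) or MLN-primed 3 (0.41). Counts for the lists of lymphoid homing and of genes low in resident memory did not change when adjusted over the list alone.

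**Figure D2:**
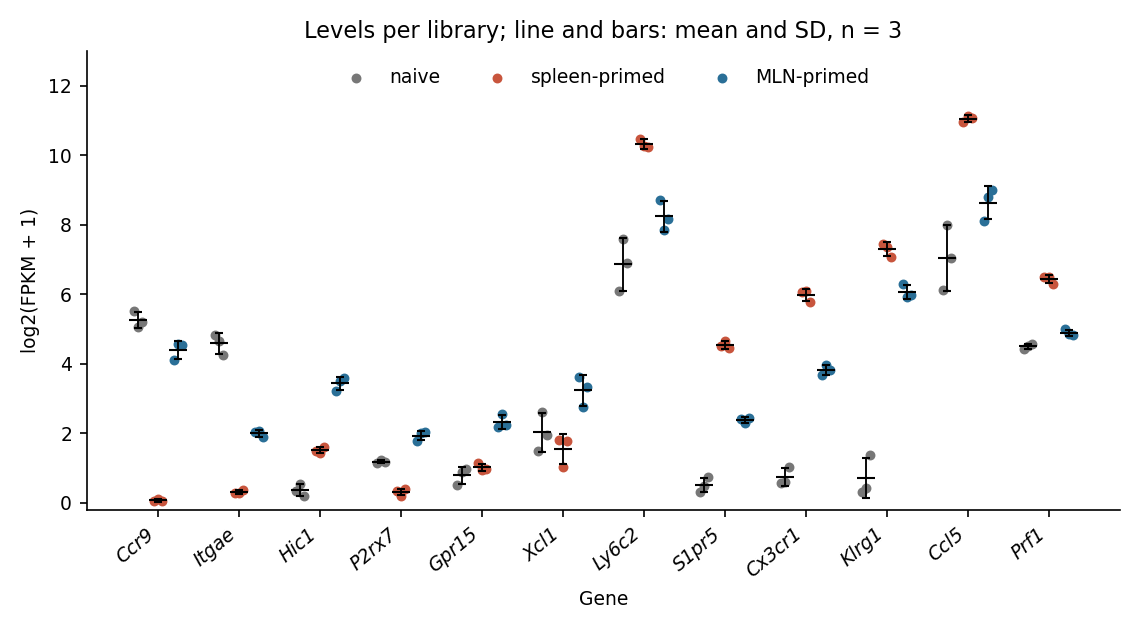
log2(FPKM + 1) of 12 genes (y axis) in each of the 9 libraries, grouped by gene (x axis) and coloured by group. Points are libraries, and lines and bars are the mean and SD of 3 libraries, with Ccr9 near 0 in spleen-primed libraries and S1pr5, Cx3cr1, Ccl5 and Prf1 highest there.

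Many, though not all, tested genes of effector function were lower in MLN-primed than in spleen-primed cells. In the terminal effector list 2 of 22 tested members were higher and 13 lower (2 higher and 15 lower adjusted over the list alone; camera, adjusted p = 1.09e-06, and adjusted p = 0.163 with an estimated correlation). The lower members included Cx3cr1 (-2.16), S1pr5 (-2.16), Klrk1 (-1.82) and Il18r1 (-1.59), and Batf (0.36) and Irf4 (0.45) were higher. The call of Irf4 ended without any single primed library except spleen-primed 3 (0.41 to 0.48) and without both spleen-primed 3 and MLN-primed 1 (0.47). It also ended with a pseudocount of 0.1 (0.49), with no filter (0.45), under median-of-ratios scaling (0.41) and after removal of the length and GC trend (0.42). Among cytotoxic effector molecules 3 of 21 tested members were higher and 10 lower (3 higher and 11 lower adjusted over the list alone; camera, adjusted p = 4.65e-04, and adjusted p = 0.163 with an estimated correlation). Perforin (Prf1) was at 28.7 ± 1.8 against 85.8 ± 6.8 FPKM (-1.55 ± 0.08, adjusted p = 7.16e-06), and the chemokine gene Ccl5 at 408 ± 121 against 2118 ± 138 FPKM (-2.42 ± 0.40, adjusted p = 0.00166). The granzyme genes Gzmb and Gzmk did not pass, at 1169 against 1499 and 308 against 358 FPKM (adjusted p = 0.126 and 0.264). Gzmb passed without naive 3 or with only the libraries of both groups fitted (-0.36 in both). Gzmk passed with the length trend of each library as a covariate (-0.22) or without both spleen-primed 3 and MLN-primed 1 (-0.49). The covariate alters only the spread and not the difference. The chemokine gene Xcl1 was higher, at 8.68 ± 2.76 against 2.0 ± 0.813 FPKM. Interferon-stimulated genes were lower, with 22 of 31 tested members lower and 0 higher at the adjusted threshold (0 higher and 23 lower adjusted over the list alone; camera, adjusted p = 5.82e-10, and adjusted p = 0.208 with an estimated correlation). Their median log2 change was -0.60, and Zbp1 (-1.20), Usp18 (-1.15) and Gbp2 (-0.99) had the smallest p-values.

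The naive and quiescent, memory precursor, CD8 T cell identity and myeloid marker lists also passed as lower in camera at its preset correlation, and did not pass with an estimated one. In the naive and quiescent list 2 of 24 tested members were higher and 12 lower (camera, adjusted p = 7.28e-05, and adjusted p = 0.171 with an estimated correlation), with Btg1 (-1.23), Slfn2 (-0.87) and Dapl1 (-1.48) among the lower and Igfbp4 (0.60) among the higher. In the memory precursor list 3 of 17 tested members were higher and 6 lower (3 higher and 7 lower adjusted over the list alone; camera, adjusted p = 0.0421, and adjusted p = 0.427 with an estimated correlation). Eomes (-1.04) was lower and Xcl1 (1.69) higher. That call ended without naive 1 (camera, adjusted p = 0.0517), without spleen-primed 3 (0.136) and without MLN-primed 1 (0.0801), and also with only the libraries of both groups fitted (0.0513) or only genes of at least 5 FPKM tested (0.0801). Without both spleen-primed 3 and MLN-primed 1 its adjusted p was 0.307 and its median log2 change -0.09, against -0.24 in the fit of all libraries. Of the 10 tested CD8 T cell identity genes, 7 were lower and 0 higher at the adjusted threshold (camera, adjusted p = 6.65e-06, and adjusted p = 0.0801 with an estimated correlation), among them Cd2 (-1.27), Cd3g (-0.56) and Cd8b1 (-0.52). The myeloid marker list was lower with 3 of 7 members (camera, adjusted p = 0.00724, and adjusted p = 0.418 with an estimated correlation), and these 3, Itgam (-1.61), Cd68 (-0.93) and Tyrobp (-1.11), are also expressed by effector T or NK cells. Except for the memory precursor list, these counts did not change when adjusted over the list alone.

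The cholesterol biosynthesis, glycolysis, heat shock and cell cycle lists passed as higher in MLN-primed cells in camera at its preset correlation, and did not pass with an estimated one. In the cholesterol biosynthesis list 20 of 24 tested members were higher and 0 lower (21 higher and 1 lower adjusted over the list alone; camera, adjusted p = 2.97e-08, and adjusted p = 0.208 with an estimated correlation), with a median log2 change of 0.52. Fdps (1.06), Sqle (0.90) and Lss (0.88) had the smallest p-values. In the glycolysis list 14 of 20 tested members were higher and 1 lower (14 higher and 2 lower adjusted over the list alone; camera, adjusted p = 4.92e-05, and adjusted p = 0.0801 with an estimated correlation), with Tpi1 (0.94), Eno1 (0.63) and Pgam1 (0.80) higher and the glucose transporter gene Slc2a3 (-0.38) lower. Of 10 heat shock genes, 5 were higher and 0 lower at the adjusted threshold (6 higher and 0 lower adjusted over the list alone; camera, adjusted p = 0.00129, and adjusted p = 0.208 with an estimated correlation), led by the mitochondrial chaperonin genes Hspd1 (1.35) and Hspe1 (1.05) and by Hsp90aa1 (1.14) and Hsp90ab1 (0.88). Of 38 cell cycle genes, 14 were higher and 0 lower, the same as adjusted over the list alone (camera, adjusted p = 0.00167, and adjusted p = 0.418 with an estimated correlation). The members that passed included Ccne1 (0.69), Mcm2 (0.39) and Cdc6 (0.49), while Pcna, Tyms, Rrm2, Ccnb1 and Birc5 were among the 24 that did not pass (adjusted p = 0.461, 0.537, 0.146, 0.123 and 0.902). Rrm2 passed without naive 2 or with only the libraries of both groups fitted (0.24 in both). The proliferation marker Mki67 ranged from 13.4 to 87.1 FPKM in spleen-primed and from 8.32 to 84.1 FPKM in MLN-primed libraries, and in each group it was lowest in the library with the most negative length trend (adjusted p = 0.797). Without spleen-primed 3 and MLN-primed 1, left out together, Mki67 was higher in MLN-primed cells (2.14). That fit cannot tell group from length trend. The slopes left per doubling of length were -0.0635 and -0.026 in spleen-primed and 0.0669 and 0.0385 in MLN-primed libraries. It also leaves out the highest spleen-primed and the lowest MLN-primed value of Mki67.

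Other lists did not pass in camera between the primed groups. Counts of higher and lower members were 8 and 1 of 19 for hypoxia and nutrient sensing, 8 and 1 of 31 for oxidative phosphorylation, 6 and 2 of 21 for lipid metabolism, 4 and 4 of 20 for activation and inhibitory receptors, 1 and 4 of 17 for the TGF-beta pathway, and 1 and 3 of 18 for immediate early genes. Adjusted over the list alone, 7 oxidative phosphorylation genes were higher and the other 5 pairs of counts were the same. Their camera adjusted p lay between 0.123 and 0.376. Members that passed included the fatty acid-binding protein gene Fabp5 (1.20), the asparagine synthetase gene Asns (0.98) and the receptor genes Tnfrsf4 (1.09) and Il2ra (0.96), all higher, and Tigit (-0.66), Ier5 (-0.82) and Smad3 (-0.55), all lower. The oxidative phosphorylation list passed without spleen-primed 1 or 2 or without MLN-primed 2 or 3 (camera, adjusted p from 0.0173 to 0.0434), and without MLN-primed 1 its adjusted p was 0.943. In fry the hypoxia and nutrient sensing list passed (adjusted p = 5.40e-04) and the other 5 did not. Of the dendritic cell and MHC class II markers, Batf3 (1.79) was higher and Itgax (-1.17) lower (camera, adjusted p = 0.56, and adjusted p = 0.785 with an estimated correlation). Lists with fewer than 5 tested members had no set test. In these, 3 of 4 NK cell genes and 2 of 3 type 17, type 2 and regulatory genes were lower, 1 of 2 B cell genes, Cd79b (0.73), was higher, and none of 4 CD4, 3 red cell and 1 stromal genes passed. Adjusted over the list alone, Pecam1, the only tested gene of the stromal list, was lower and the other counts of these lists were the same. No plasma cell, epithelial or gamma delta marker was tested.

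**Figure D3:**
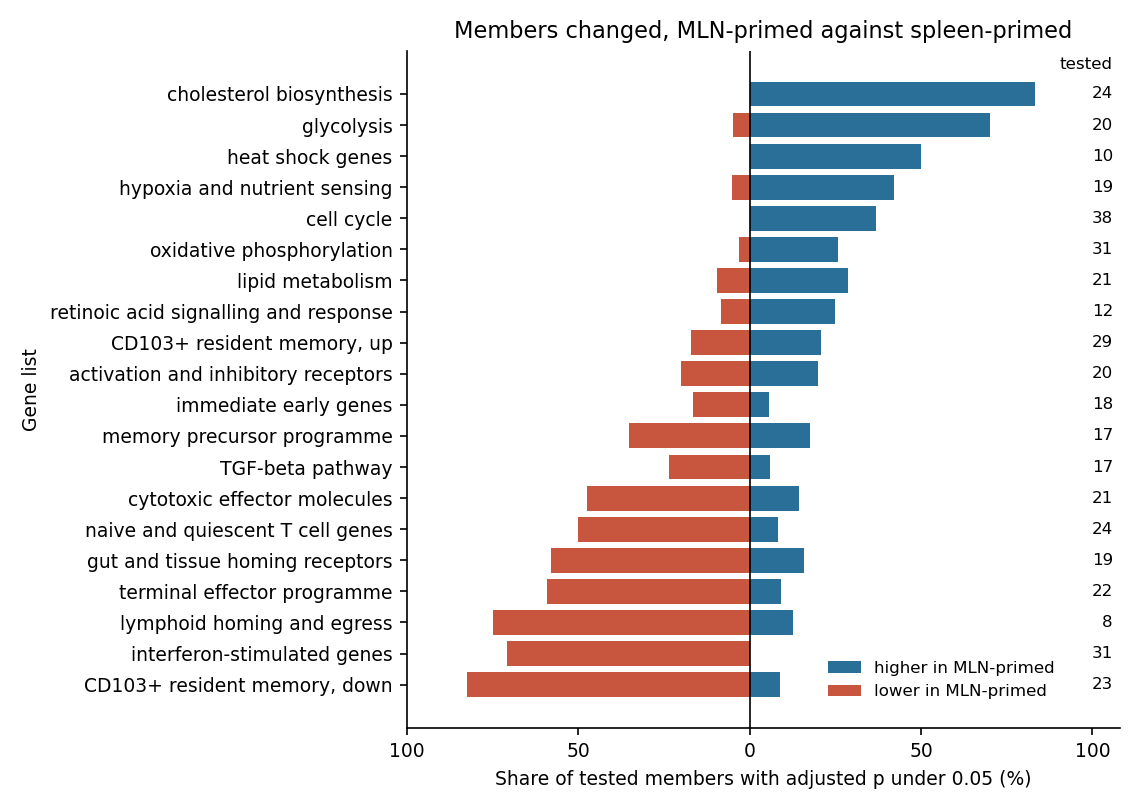
Share of tested members (x axis, percent) of each gene list with at least 5 tested members (y axis) that were higher (right) or lower (left) in MLN-primed than in spleen-primed cells at adjusted p under 0.05, with the number tested at the right. Cholesterol biosynthesis has the longest bar to the right, with 20 of 24 members.

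Over all genes, 3093 of 10185 tested differed between the primed groups (limma, adjusted p under 0.05), 1760 higher and 1333 lower in MLN-primed cells. The higher share was 56.9% as deposited, 47.8% under median-of-ratios scaling, 51.5% after quantile normalisation and 50.5% after removal of the length and GC trend, so the majority turned under median-of-ratios scaling alone. The change exceeded 1 on the log2 scale for 83 higher and 103 lower genes. Beside those given above, the largest rises under the naming rule were those of Car2 (1.84), Batf3 (1.79), Lztfl1 (1.69), Rangrf (1.64), Erdr1 (1.47), Arhgdig (1.46) and Srm (1.39). Car2 encodes a carbonic anhydrase and Srm spermidine synthase, and Lztfl1 is a neighbour of Ccr9 on chromosome 9 (123694404 to 123717625, minus strand, RefSeq). A longer GENCODE model of Ccr9, starting at 123678439, spans Lztfl1 on the other strand without sharing exonic bases with it. The largest falls further included S100a4 (-2.26), Sema4a (-2.04), Ly6c1 (-2.02), AB124611 (-2.02) and Wdr95 (-1.94), with S100a4, a calcium-binding protein gene, at 582 ± 26.3 against 2789 ± 242 FPKM. Erdr1 was at 41.1 ± 18.1 against 13.3 ± 2.72 FPKM, and its call ended without MLN-primed 2 (log2 change 1.33) or without MLN-primed 3 (1.19).

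Spleen-primed and naive cells were compared to describe the response to priming in the spleen, both groups coming from that organ. Gzmb was at 1499 ± 153 against 2.3 ± 0.899 FPKM, a log2 change of 8.86 ± 0.16 (SE; limma, adjusted p = 5.89e-11), and Gzmk at 358 ± 54.6 against 0.113 ± 0.0322 FPKM (8.32 ± 0.14, adjusted p = 3.98e-11). The lymph node chemokine receptor gene Ccr7 fell from 346 ± 16.0 to 8.05 ± 0.972 FPKM (-5.26 ± 0.12, adjusted p = 2.35e-10). Ccr9 and Itgae fell by 5.19 and 4.27 on the log2 scale (adjusted p = 7.98e-10 and 2.06e-09).

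All 38 tested cell cycle genes were higher in spleen-primed cells (camera, adjusted p = 3.26e-16, and adjusted p = 0.107 with an estimated correlation), with a median log2 change of 4.34 and Birc5 (6.94), Ccna2 (6.70) and Ccnb1 (6.19) as examples. In the terminal effector list 20 of 22 tested members were higher and 0 lower (camera, adjusted p = 6.11e-07, and adjusted p = 0.112 with an estimated correlation), among them Klrg1 (6.59), Cx3cr1 (5.24) and Tbx21 (4.96). Among cytotoxic effector molecules 17 of 21 tested members were higher and 2 lower (camera, adjusted p = 6.57e-04, and adjusted p = 0.14 with an estimated correlation). Gzma (7.73) and Ccl5 (4.0) were higher and Lta (-1.07) lower. Gut and tissue homing receptors were higher for 14 of 19 members and lower for 3 (camera, adjusted p = 0.00215, and adjusted p = 0.108 with an estimated correlation), with Itgb1 (4.06), Ccr2 (5.30) and Itga4 (1.60) higher and Ccr9 and Cxcr4 (-1.53) lower. Among activation and inhibitory receptors 14 of 20 tested members were higher and 4 lower (camera, adjusted p = 0.00551, and adjusted p = 0.107 with an estimated correlation). Tigit (4.84), Pdcd1 (4.55) and Lag3 (4.45) were higher and Cd69 (-2.66) and Tox (-2.24) lower. Of the metabolic lists 3 rose as well. All 31 oxidative phosphorylation genes were higher (camera, adjusted p = 9.85e-07, and adjusted p = 0.412 with an estimated correlation). Of 20 glycolysis genes, 16 were higher and 2 lower (camera, adjusted p = 9.78e-04, and adjusted p = 0.108 with an estimated correlation), and 17 of 24 cholesterol biosynthesis genes were higher and 0 lower (camera, adjusted p = 8.68e-04, and adjusted p = 0.412 with an estimated correlation). Examples are Cox5b (1.92), Tpi1 (2.49) and Sqle (1.72), and the lower glycolysis genes were Pdk1 (-3.10) and Bnip3 (-0.97).

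All 24 naive and quiescent T cell genes were lower in spleen-primed cells (camera, adjusted p = 3.90e-13, and adjusted p = 0.107 with an estimated correlation), with a median log2 change of -3.15 and Tdrp (-5.99), Igfbp4 (-5.56) and Tcf7 (-4.42) as examples. In the memory precursor list 1 of 17 tested members were higher and 15 lower (camera, adjusted p = 6.42e-07, and adjusted p = 0.108 with an estimated correlation), the higher gene being Eomes (2.02). Of 8 genes of lymphoid homing and egress, 7 were lower and 1, S1pr4 (0.75), higher (camera, adjusted p = 4.83e-04, and adjusted p = 0.107 with an estimated correlation). S1pr4 did not pass after quantile normalisation (0.17). Of 17 TGF-beta pathway genes, 12 were lower and 2 higher (2 higher and 13 lower adjusted over the list alone; camera, adjusted p = 4.83e-04, and adjusted p = 0.375 with an estimated correlation). Smad7 (-2.54) and Ldlrad4 (-2.10) were lower and Smad3 (1.62) and Tgfb1 (0.39) higher. The change of Tgfb1 turned to -0.0296 after quantile normalisation. Of 18 immediate early genes, 15 were lower and 0 higher (camera, adjusted p = 2.77e-04, and adjusted p = 0.412 with an estimated correlation), among them Egr1 (-2.44) and Zfp36 (-2.62). In naive libraries 1, 2 and 3, Fos was at 3.22, 187 and 50.3 FPKM. Of 31 interferon-stimulated genes, 20 were lower and 3 higher (camera, adjusted p = 1.39e-04, and adjusted p = 0.412 with an estimated correlation). Rtp4 (-3.03) and Oasl2 (-2.41) were lower and Gbp3 (1.51) higher.

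Further lists did not pass in camera. Higher and lower counts were 5 and 7 of 12 for retinoic acid signalling and response, 11 and 15 of 29 and 10 and 12 of 23 for the lists that are high and low in CD103+ resident memory, 2 and 6 of 10 for CD8 T cell identity, 6 and 0 of 10 for heat shock genes, 5 and 9 of 19 for hypoxia and nutrient sensing, and 10 and 6 of 21 for lipid metabolism. Their camera adjusted p lay between 0.105 and 0.555. The CD8 T cell identity list passed, as lower, after quantile normalisation (camera, adjusted p = 0.00166), after trend removal (0.0197) and with only genes of at least 5 FPKM tested (0.0494). Among these members Hic1 (1.15), Itgb7 (1.19) and Fabp5 (3.75) were higher and Rarg (-2.15) lower. Of 6 dendritic cell and MHC class II markers, the 4 MHC class II genes were lower, with H2-Aa at 0.935 ± 0.736 against 33.3 ± 8.53 FPKM, and Itgax (5.55) and Batf3 (1.43) were higher (camera, adjusted p = 0.155, and adjusted p = 0.518 with an estimated correlation, and adjusted p = 0.0126 with no filter). Of 7 myeloid markers, 4 were lower, with Lyz2 and S100a8 among them, and Itgam (4.57) and Cd68 (3.02) were higher (camera, adjusted p = 0.398, and adjusted p = 0.738 with an estimated correlation). In fry all of these 9 lists except the one low in resident memory passed (adjusted p from 8.58e-05 to 0.0197). As fry does not set a list against other genes, and 75.8% of all tested genes passed here, this singles out no list. In lists without a set test, 3 of 4 NK cell genes were higher, and 3 of 4 CD4 genes were lower and 1 higher. Of the type 17, type 2 and regulatory genes 1 of 3 went each way, and of the B cell genes 1 of 2. Pecam1 (-3.13), the only tested gene of the stromal list, was lower, and no red cell gene passed. As the endothelial markers Cdh5 and Kdr were under 1 FPKM in every library, Pecam1 alone is no sign of stroma or endothelium. Except for the TGF-beta pathway, the counts of this comparison did not change when adjusted over the list alone.

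In total, 7718 genes differed between spleen-primed and naive cells (limma, adjusted p under 0.05), 4387 higher and 3331 lower, with 1755 and 1150 of these beyond 1 on the log2 scale. The higher share was 56.8% as deposited and 46.6% after quantile normalisation, which moved the median log2 change of all genes from 0.10 to -0.07. It was 50.4% under median-of-ratios scaling and 46.3% after removal of the length and GC trend. Of the genes called as deposited, 92 passed in the other direction after quantile normalisation and 105 after trend removal. Further genes under the naming rule were S100a4 (7.78), S100a6 (6.96), Lgals3 (6.91) and Ube2c (6.75), all higher, and St6gal1 (-5.95), Fam101b (-5.24), Nsg2 (-5.09), Atp1b1 (-4.99) and Dapl1 (-4.95), all lower.

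MLN-primed and naive cells differ both in priming and in the organ they came from. Gzmb was at 1169 ± 87.1 against 2.3 ± 0.899 FPKM, a log2 change of 8.50 ± 0.16 (SE; limma, adjusted p = 6.40e-11), and the metallothionein gene Mt1 at 201 ± 12.4 against 0.315 ± 0.304 FPKM (7.29 ± 0.17, adjusted p = 2.43e-10). Tcf7, a transcription factor gene of naive and memory T cells, fell from 775 ± 35.1 to 21.2 ± 4.78 FPKM (-5.15 ± 0.20, adjusted p = 5.77e-09). Ccr9 and Itgae were lower than in naive cells here too, by 0.85 and 2.59 on the log2 scale in size (adjusted p = 3.44e-04 and 6.05e-08), while Hic1 (3.07), Gpr15 (1.54) and P2rx7 (0.75) were higher.

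All 38 cell cycle genes were higher (camera, adjusted p = 1.18e-14, and adjusted p = 0.107 with an estimated correlation), with a median log2 change of 4.71. In the terminal effector list 18 of 22 tested members were higher and 3 lower (camera, adjusted p = 2.68e-04, and adjusted p = 0.271 with an estimated correlation). Klrg1 (5.36) and Tbx21 (4.42) were higher and Klrd1 (-1.26) lower. Among cytotoxic effector molecules 16 of 21 tested members were higher and 2 lower (camera, adjusted p = 0.0089, and adjusted p = 0.272 with an estimated correlation). Gut and tissue homing receptors were higher for 15 of 19 members and lower for 4 (camera, adjusted p = 0.0144, and adjusted p = 0.169 with an estimated correlation). Activation and inhibitory receptors were higher for 16 of 20 and lower for 4 (camera, adjusted p = 0.00558, and adjusted p = 0.107 with an estimated correlation), with Lag3 (4.40) and Il2ra (4.38) higher. Both calls ended when only genes of at least 5 FPKM in 3 libraries were tested. Of 31 oxidative phosphorylation genes 30 were higher and 0 lower (camera, adjusted p = 2.91e-06, and adjusted p = 0.366 with an estimated correlation). Of 20 glycolysis genes 16 were higher and 2 lower (camera, adjusted p = 3.49e-04, and adjusted p = 0.107 with an estimated correlation), and of 24 cholesterol biosynthesis genes 23 were higher and 0 lower (camera, adjusted p = 1.46e-05, and adjusted p = 0.31 with an estimated correlation). Of 10 heat shock genes 8 were higher and 0 lower (camera, adjusted p = 0.0304, and adjusted p = 0.365 with an estimated correlation), led by Hsp90aa1 (3.01) and Hspd1 (2.73), a call that ended without naive 3 (camera, adjusted p = 0.057). Other examples are Tpi1 (3.43), Idi1 (3.06), Asns (3.89) and Fabp5 (4.95).

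All 24 naive and quiescent T cell genes were lower (camera, adjusted p = 2.35e-13, and adjusted p = 0.107 with an estimated correlation), with a median log2 change of -3.70. Memory precursor genes were lower for 15 of 17 members and higher for 2 (camera, adjusted p = 1.32e-06, and adjusted p = 0.107 with an estimated correlation), the higher ones being Xcl1 (1.21) and Eomes (0.98). Xcl1 did not pass after removal of the length and GC trend (0.54). Lymphoid homing genes were lower for 7 of 8 and higher for 1 (camera, adjusted p = 1.89e-04, and adjusted p = 0.107 with an estimated correlation). TGF-beta pathway genes were lower for 13 of 17 and higher for 2 (camera, adjusted p = 3.49e-04, and adjusted p = 0.315 with an estimated correlation), and immediate early genes lower for 16 of 18 and higher for 0 (camera, adjusted p = 1.89e-04, and adjusted p = 0.353 with an estimated correlation). Of 31 interferon-stimulated genes 26 were lower and 1, Gbp3 (0.95), higher (camera, adjusted p = 2.51e-07, and adjusted p = 0.31 with an estimated correlation), with Rtp4 (-3.83) and Ifit1 (-3.44) as examples. CD8 T cell identity genes were lower for 7 of 10 and higher for 0 (camera, adjusted p = 0.00205, and adjusted p = 0.107 with an estimated correlation), with Cd3d (-1.36) and Cd2 (-1.30) among them. Lists that did not pass in camera had higher and lower counts of 6 and 5 of 12 for retinoic acid signalling and response, 13 and 15 of 29 and 9 and 13 of 23 for genes high and low in CD103+ resident memory, 7 and 7 of 19 for hypoxia and nutrient sensing, and 12 and 5 of 21 for lipid metabolism (12 higher and 6 lower adjusted over the list alone). Their camera adjusted p lay between 0.0965 and 0.704. Of the dendritic cell and MHC class II list 4 of 6 and of the myeloid list 5 of 7 members were lower, and 2 were higher in each (camera, adjusted p = 0.174 and 0.255, and 0.00882 and 0.0281 with no filter), and H2-Aa was at 0.287 ± 0.10 against 33.3 ± 8.53 FPKM. In fry 5 of these 7 lists passed, all but retinoic acid signalling and myeloid markers (adjusted p from 5.01e-05 to 0.00391). Here 78.7% of all tested genes passed, so a pass in fry singles out no list. In lists without a set test, 3 of 4 NK cell genes were higher and 1 lower, and 3 of 4 CD4 genes lower and 1 higher. Of the type 17, type 2 and regulatory genes 1 of 3 went each way, and 1 of 2 B cell genes was higher. Pecam1, the only tested gene of the stromal list, was lower, and no red cell gene passed. Except for lipid metabolism, the counts did not change when adjusted over the list alone.

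In total, 8020 genes differed between MLN-primed and naive cells (limma, adjusted p under 0.05), 4635 higher and 3385 lower, with 2122 and 1321 of these beyond 1 on the log2 scale. The higher share was 57.8% as deposited, 50.4% under median-of-ratios scaling, 48.1% after quantile normalisation and 48.2% after trend removal, and 114 and 90 of the genes called passed in the other direction in the last 2. Quantile normalisation moved the median log2 change of all genes from 0.15 to -0.04 and median-of-ratios scaling moved it to -0.01. Every list called in the naive comparisons kept its direction and its call under both scalings. Further genes under the naming rule were Gzmk (8.10), Gzma (7.26), Birc5 (6.96), Rrm2 (6.79), Ccna2 (6.73), Ube2c (6.62), Lgals3 (6.49) and Tk1 (6.48), all higher, and Dapl1 (-6.43), St6gal1 (-6.09), Tdrp (-5.95), Nsg2 (-5.70), Il6ra (-4.97), Igfbp4 (-4.95), Fam101b (-4.82) and Ccr7 (-4.80), all lower.

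The responses of both primed groups against naive cells were close across genes. Their log2 changes correlated at 0.957 (Pearson, across 10185 genes, which are not independent replicates), with a covariance of 1.46. Both comparisons use the same 3 naive libraries. Simulated unchanged groups against shared controls gave a mean correlation of 0.498 and a mean covariance of 0.0146, so the covariance above the simulated one was 1.45. In both comparisons 4037 genes were higher, against 1996 for independent lists, and 2904 were lower, against 1107. The simulated overlap was at most 0 genes. The simulations leave out the effects, and the independent lists leave out the shared controls. The 3 naive libraries cannot be split into parts of 2 each, so part of the overlap beyond independent lists may come from the shared controls. For the covariance, the spread among shared controls gave 0.0146 of 1.46 in the simulation. A factor common to all 3 naive libraries was not simulated. The same sign was found for 90.3% of genes, against 66.7% in the simulation. Gzmb, Gzmk, Birc5 and Lgals3 were among the 10 largest rises and Tdrp, St6gal1, Igfbp4 and Ccr7 among the 10 largest falls of both comparisons under the naming rule. Opposite directions passed the test for 63 genes.

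**Figure D4:**
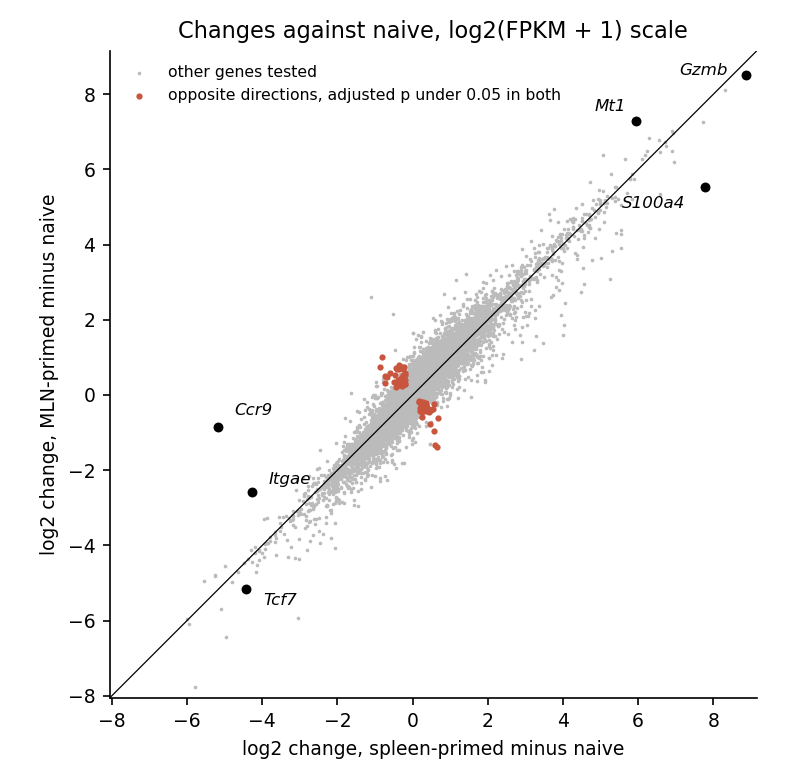
log2 change of each of the 10185 genes tested against naive, in spleen-primed (x axis) and MLN-primed (y axis) cells, on the log2(FPKM + 1) scale. The line marks equal change, red points are the 63 genes that passed in opposite directions, and Ccr9 and Itgae lie above the line because they were lower than naive by less in MLN-primed cells.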

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

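The tests on transcript length, on markers of other cells and on the Ccr9 region were chosen after the results were seen, except that of cell division; the splits of the libraries were planned.

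Because 63 genes passed against naive in opposite directions in the primed groups, they were singled out for a closer look. All 63 also passed between these groups, which opposite calls in one fit make all but certain. Some changes against naive were small, such as 0.17 and -0.18 for Dazap2. Quantile normalisation moved the median log2 change of all genes from 0.10 to -0.07 in spleen-primed and from 0.15 to -0.04 in MLN-primed cells against naive. Whether the opposite directions hold under it was not tested. Of the 63 genes, 36 were higher and 27 lower in MLN-primed cells. The 5 largest differences, given as log2 change of MLN-primed minus spleen-primed cells, were those of Sema4a (-2.04), Lmna (-1.91), Car2 (1.84), P2rx7 (1.62) and Fcgrt (-1.50). Sema4a was at 49.3 FPKM in naive, 78.6 in spleen-primed and 18.2 in MLN-primed cells, and Car2 at 3.9, 1.51 and 8.09 FPKM.

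With 10 splits of 6 libraries, no share under 0.05 can be reached. Between the primed groups the real split called 3093 genes and the highest other split 843, with 1 of 10 splits as large. That other split set spleen-primed 1 and 2 and MLN-primed 1 against the rest, which follows the length trend. For spleen-primed against naive the real split called 7718 genes and the highest other 1, with 1 of 10 as large, and for MLN-primed against naive 8020 and 0, with 1 of 10 as large. Each other split has naive and primed libraries on both sides, so their large difference enters the spread within sides. Near 0 gene calls were thus built in there, and the gap carries no weight against chance. For gene lists the values were 14 and 15 between the primed groups (2 of 10 as large), 14 and 14 for spleen-primed against naive (3 of 10) and 16 and 14 for MLN-primed against naive (1 of 10). Between the primed groups and for spleen-primed against naive, other splits thus called as many lists or more. This is no evidence against the real groups, because every other split puts 2 libraries of a group with 1 of the other. Such splits keep part of the real difference, which a list test can still call. The numbers of lists called thus cannot tell the real groups from chance.

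Libraries within the primed groups differed along a shared axis that held 47.8% of the variance within groups. Differing cell division as its sole cause was argued against by 38 cell cycle genes. Their SD within the primed groups grew with transcript length (Spearman rho 0.595, permutation p = 0.0001 of 100000 resamples), from a median of 0.0641 in the shorter genes to 0.139 in the longer ones. The permutation treats these genes as independent, which they are not. A length trend gives such growth whether or not division differs too, and no length-matched genes were compared. Division as a further cause thus stays open. Across genes, which are not independent replicates, the axis correlated with log2 transcript length at 0.422, so a length trend may account for part of it, 17.8% of its variance. As the whole cause of the calls between the primed groups, the trend was argued against, because 2901 of the 3093 genes (93.8%) were still called in the same direction after its removal. What makes up the rest of the axis stays open.

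The 4 MHC class II genes of the marker list that were tested were higher in naive than in primed libraries. So were the related genes H2-Ob, H2-Oa and H2-DMa, at 26.8, 23.5 and 21.2 FPKM in naive cells. They were at 0.11, 5.12 and 5.19 FPKM in spleen-primed and 0.0573, 3.88 and 4.42 FPKM in MLN-primed cells. B cells as the source were argued against, since 1 of 11 B cell markers, Fcrla, had every naive library above every primed library, and Ms4a1 and Cd79a reached at most 0.134 and 0.335 FPKM in any library. The B cell marker Cd79b was higher, at 12.5 FPKM in naive, 7.02 in spleen-primed and 12.3 in MLN-primed cells, and was not separated. The immunoglobulin constant genes had no value. Of 22 dendritic cell and myeloid markers, 13 were separated in this way. Chance gives 1.19% only for a gene that does not differ. Over all 10185 genes tested, 3331 were lower in spleen-primed and 3385 in MLN-primed than in naive cells, so 1.19% is no fair baseline. These markers were also noticed together with the MHC class II genes, so their number tests no source. Cd74 was at 55.4 ± 15.2, Lyz2 at 5.79 ± 3.83 and S100a8 at 11.2 ± 8.94 FPKM in naive cells, while the list members Itgax, Itgam, Cd68 and Batf3 were higher in primed cells. The labels state no gate, and both a trace of dendritic or myeloid cells and expression by the naive T cells themselves stay open. How these genes varied among the naive libraries is given at the end.

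Lztfl1 followed Ccr9, at 7.92 ± 0.526 FPKM in naive, 1.86 ± 0.0849 in spleen-primed and 8.29 ± 1.16 in MLN-primed cells. Reads of spliced Ccr9 transcripts counted for Lztfl1 were argued against, because the annotated exons of both genes share 0 bases, and 49585 bases lie between their RefSeq ends. A change of the whole region was argued against as well, since 0 of the 3 neighbours Sacm1l, Cxcr6 and Fyco1 were higher in both naive and MLN-primed than in spleen-primed cells. Unspliced reads from the longer Ccr9 model stay open, as the use of strand is not given, and joint regulation of the pair, which may also account for the pattern, was not tested.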

How the results depend on the processing

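The length and GC trend removal, the length covariate and the fit without spleen-primed 3 and MLN-primed 1 were chosen after the data were seen. Counts of changed genes stayed within 1.5 times of the value reported in every alternative run, and no named gene or list that had passed changed direction except Tgfb1 in spleen-primed against naive, at -0.0296 after quantile normalisation. With each library left out in turn, counts were 2139 to 3196 for MLN-primed against spleen-primed, 7207 to 7911 for spleen-primed against naive and 7654 to 8095 for MLN-primed against naive. Without both spleen-primed 3 and MLN-primed 1 they were 3892, 8013 and 8115, after trend removal 3539, 7836 and 8109, and with the length covariate 4311, 8280 and 8507. The covariate averages out within each group, so it leaves group differences unchanged and alters only the spread. Between the primed groups it kept all 3093 calls and added 1218, and these gains are no separate support. In the fit without both libraries the primed groups also differ in length trend, so its gained calls between them cannot be told from that trend. With an estimated correlation the lists called fell from 14, 14 and 16 to 0, 0 and 0, and fry called 16, 22 and 21; both differ from the preset camera test by construction. The correlation of both responses was 0.96 with a pseudocount of 0.1, and 0.951 to 0.958 with a library left out, lowest without MLN-primed 1; the cause was not tested. The replicate block gave 3382, 7928 and 8207 genes. Of 9 pairs of libraries with the same number, 7 deviated together at over 0.1, and all 9 ranged from -0.241 to 0.645. Of 9 libraries, 5 correlated best with their own number. These values do not exclude a shared factor behind the numbers. The main fit has no block because the labels do not say what the numbers mark. Between the primed groups the memory precursor list lost its call in 6 alternatives and oxidative phosphorylation gained one in 4. Calls of named genes there were lost 29 times in planned and 2 times in added alternatives and gained 5 and 5 times. Against naive, 3 lists lost a call in 1 alternative each (MLN-primed), CD8 T cell identity gained one under quantile normalisation, trend removal and the higher filter (spleen-primed), and with no filter dendritic cell markers gained one in both comparisons and myeloid markers in MLN-primed cells. Low genes are limited by the pseudocount and the unknown depth.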

Other observations

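The gene families here were defined by symbol after the data were seen, and no hypothesis beyond the tests given with the patterns above was tested.

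Several gene families were higher in MLN-primed than in spleen-primed cells, and not all families screened are given here. Of the nucleolar and rRNA processing proteins, 56 of 71 were higher and 0 lower, with a median log2 change of 0.56 (camera, adjusted p = 2.47e-17, and adjusted p = 0.0814 with an estimated correlation). Of the mitochondrial ribosomal proteins, 45 of 76 were higher and 0 lower, with a median log2 change of 0.29 (camera, adjusted p = 3.44e-09, and adjusted p = 0.286 with an estimated correlation). Of the cytosolic tRNA synthetases, 14 of 17 were higher and 0 lower, with a median log2 change of 0.42 (camera, adjusted p = 4.53e-06, and adjusted p = 0.0814 with an estimated correlation). Of the subunits of the CCT chaperonin, which folds actin and tubulin, 7 of 7 were higher and 0 lower, with a median log2 change of 0.58 (camera, adjusted p = 3.62e-05, and adjusted p = 0.193 with an estimated correlation). Of the enzymes of nucleotide synthesis, 17 of 19 were higher and 0 lower, with a median log2 change of 0.67 (camera, adjusted p = 1.80e-09, and adjusted p = 0.116 with an estimated correlation). Of those of polyamine synthesis, which include Srm, 5 of 6 were higher and 0 lower, with a median log2 change of 0.66 (camera, adjusted p = 6.57e-04, and adjusted p = 0.152 with an estimated correlation). Of the translation initiation factors, 24 of 53 were higher and 1 lower, with a median log2 change of 0.31 (camera, adjusted p = 5.99e-05, and adjusted p = 0.0683 with an estimated correlation). The medians of these 7 families kept their sign under both scalings and after removal of the length and GC trend. The cytosolic ribosomal proteins did not pass, and 2 of 81 were higher and 0 lower, with a median log2 change of 0.05 (camera, adjusted p = 0.478, and adjusted p = 0.933 with an estimated correlation). Their genes were lower than in naive cells for 68 of 81 members in spleen-primed and 69 of 81 in MLN-primed cells, with median log2 changes of -0.85 and -0.82 as deposited, -0.97 and -0.97 under median-of-ratios scaling, -0.39 and -0.24 after quantile normalisation, and -1.29 and -1.33 after trend removal. With an estimated correlation the family did not pass in either (camera, adjusted p = 0.506 and 0.429).

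Other families were lower in MLN-primed cells. Of the killer lectin-like receptors, 0 of 9 were higher and 9 lower, with a median log2 change of -1.23 (camera, adjusted p = 4.53e-06, and adjusted p = 0.152 with an estimated correlation). Of the guanylate-binding and IRG GTPases, which act against intracellular pathogens, 0 of 14 were higher and 14 lower, with a median log2 change of -0.62 (camera, adjusted p = 3.68e-08, and adjusted p = 0.152 with an estimated correlation). Of the classical and related MHC class I genes, whose near-identical copies can share reads, 0 of 15 were higher and 9 lower, with a median log2 change of -0.65 (camera, adjusted p = 9.06e-07, and adjusted p = 0.0814 with an estimated correlation). Of the annexins, 0 of 7 were higher and 6 lower, with a median log2 change of -0.50 (camera, adjusted p = 4.60e-04, and adjusted p = 0.0814 with an estimated correlation). Of the GIMAP GTPases, which are tied to lymphocyte survival, 0 of 8 were higher and 6 lower, with a median log2 change of -0.30 (camera, adjusted p = 6.22e-04, and adjusted p = 0.0814 with an estimated correlation). The medians of these 5 families between the primed groups kept their sign under both scalings and after trend removal.

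Immediate early genes varied among the naive libraries, with Fos at 3.22, 187 and 50.3 FPKM and Jun at 3.13, 99.8 and 24.8 FPKM in naive 1, 2 and 3. Globin transcripts varied within every group, with Hba-a1 between 0.314 and 32.8 FPKM among the MLN-primed libraries. In naive 1 the MHC class II genes stood at 0.51 to 0.643 times the mean of naive 2 and 3, and H2-Oa, H2-Ob and H2-DMa at 0.906 to 1.05 times. The myeloid marker list was lowest in naive 1 too, with a mean log2(FPKM + 1) of 0.898, 1.52 and 1.82 in naive 1, 2 and 3. S100a8 was at 1.82, 12.1 and 19.6 FPKM and Lyz2 at 2.12, 5.5 and 9.75 FPKM in these libraries. Of the dendritic cell and myeloid markers with every naive library above every primed library, only Emr1 and Zbtb46 were not lowest in naive 1.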
